A study of Mus musculus with 2 samples.

How the data were processed

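Naive CD8 T cells from the spleen of C57BL/6 mice were stimulated for 2 days with plate-bound antibodies to the T cell receptor β chain (3 µg/ml) and to CD28 (1 µg/ml) in the presence of interleukin-2 (10 ng/ml), per the labels' protocols. Prednisolone, a synthetic glucocorticoid, was added at 1 µM to one culture and vehicle to the other. The cells were then moved to a new plate and kept in interleukin-2 for 3 more days, and RNA was taken on day 5. Total RNA (100 ng) was amplified and labelled with the dye Cy3 for a 1-colour Agilent mouse array, per the labels. There was 1 array per condition and 2 arrays in all, so no test between conditions, no p-value and no estimate of the spread between cultures was possible.

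The deposited scanner files hold, per the file headers, the linear intensity of each spot as written by Agilent Feature Extraction 12.0.3.1. The processed signal is an intensity that the scanner software had already background-subtracted and detrended within the array. The deposited files do not put it on a common scale between arrays. The same files give the spot's median brightness, its local background, the software's own error of the processed signal and yes-or-no flags for saturation, for being well above background and for being an outlier. Both arrays lay on the same slide and carry the same scan date, protocol and detector voltage. A second deposited table of intensity values is the processed signal multiplied by 1 constant per array, 0.792 for vehicle and 0.858 for prednisolone, on a linear scale and not centred, with column medians of 16.2 and 16.4. How the submitters chose these constants is not given in the sources used here. All columns of per-sample values could be tied to a sample.

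Each array carried 59305 non-control spots of 56605 probes. On the vehicle array 31744 spots (53.5%) were well above background, and on the prednisolone array 31730 (53.5%). No spot was saturated. Outlier flags fell on 4270 spots (7.20%) of the vehicle array and 5291 (8.92%) of the prednisolone array. The precision is limited by the number of arrays.

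The main setting was log2 of the processed signal minus the array's 75th percentile over non-control spots, which were 400.4 and 386.9 intensity units for vehicle and prednisolone. Control spots and spots with an outlier flag were left out, which removed 5879 probes, and the spots of one probe were averaged on the log2 scale. The scanner files give transcript accessions and no gene symbols. Accessions without version were matched to a RefSeq gene table of assembly GRCm38.p6. It named 33767 probes and left 22838 unnamed, 8925 of which carry Ensembl names. The headers name the older build mm9, so no coordinates are given. Of 23462 genes on the array, 1684 had only probes left out by the flags. A gene's value is the mean of its probes that were well above background and not saturated on both arrays, and 11969 genes had one. The 3912 genes with more than 1 such probe have the range of their probes in the results. Where a gene was well above background on 1 array only, a bound was computed for its brightest probe: its value against the higher of the probe's own value and the lowest value well above background on the other array. It is written "at least N-fold" (555 genes brighter and 614 dimmer with prednisolone). The other 8640 genes with a usable probe were not well above background on either array, or had a bound under 1-fold, and have no value. All differences are prednisolone minus vehicle.

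Errors are technical. The software's error per gene is given as ± on the log2 scale. A second estimate came from 281 probes printed 10 times each. A difference of at least 2-fold (1 on the log2 scale) was counted, without a test. Before the data were examined, 36 gene lists were fixed from general knowledge. For each, the median log2 difference of the measured members was placed among the medians of 10000 random lists of the same size, matched in 20 bins of brightness. A list was said to stand apart when this percentile was under 2.5 or over 97.5. The 95% interval of a median comes from 2000 resamples of the members and covers the spread among members only. The percentile treats genes as exchangeable, and lists can share members. The genes named in the text followed a rule fixed before the data were examined. It takes the 10 genes with the highest and the 10 with the lowest difference (leaving out predicted-gene, clone and accession-like symbols), the 4 largest bounds in each direction, up to 2 members at each end of a list among those at least 2-fold apart or otherwise the member farthest from 0, and 31 anchor genes. Genes named outside this rule are said to be so. Some genes, 1 of the anchors among them, are not reported here. A further 11 lists were chosen after the data were seen.

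The procedure was tested on simulated data made from the real vehicle array with noise of 0.1 (SD, log2) and 200 changed genes, 40 at each of 5 sizes, among 12949 genes with a value. All 40 genes at 2.5-fold and all 40 at 4-fold up were counted at the 2-fold threshold, and none of the 40 at 1.25-fold was. At 0.4-fold 32 of 40 and at 0.25-fold 39 of 40 were counted. The missed genes were dim ones that dropped below background, for which only a bound under 2-fold could be given. None of 12749 unchanged genes passed. Of 200 random lists of 20 genes, 10 stood apart, and of 20 lists shifted by 0.15 all did. In the real data the log2 differences had an SD of 0.73, well above this noise. For the real glycolysis list, random lists reached from −0.16 to 0.20, so a shift of 0.15 would lie inside them. The simulation therefore does not give the rate of false calls or the smallest detectable list shift in the real data.

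The alternatives tried were 5 other scalings (median of measured probes, quantile, none, 8 spike-in control probes, and the deposited table), normexp background correction with an offset of 50, stricter and no filters on dim probes, the brightest probe per gene, flagged spots kept, other thresholds, unmatched random lists, and members at their bound. Removal of a brightness trend and of a position trend were added after the data were seen. The alternative fixed before the data were examined named the mean spot brightness for normexp. It was run on the median spot brightness instead, with the median local background, which is a departure from that plan. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.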

Results

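Gene expression was measured on 2 arrays, both of mouse CD8 T cells on day 5 of culture. One culture had received prednisolone, a synthetic glucocorticoid, during the 2 days of stimulation through the T cell receptor and CD28, and the other had received vehicle. The comparison asks which differences in transcript level were present 3 days after the cells were moved to a new plate. Glucose metabolism and the immune response were in view. Addition of the drug is described only for the 2 days of stimulation, and whether any of it was carried over was not measured. There were 1 vehicle and 1 prednisolone array, with no replicates, so no difference below was tested between cultures. On each array 53.5% of the spots were well above background. Values are log2 differences, prednisolone minus vehicle, and ± is the scanner software's error for the 2 arrays.

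With prednisolone, the medians of the lists of glycolysis and glucose uptake, hypoxia-inducible factor (HIF) targets, cholesterol and fatty acid synthesis, and interferon-stimulated genes were lower than those of random lists. The medians of glucocorticoid receptor targets, Myc and ribosome biogenesis, and the unfolded protein response were higher. The glucose transporter gene Slc2a3 was 6.39-fold lower and the interferon-γ gene Ifng was 7.04-fold lower. The glucocorticoid-induced gene Fkbp5 was 5.94-fold higher. Of 13138 genes with a value, 903 (6.87%) were at least 2-fold higher and 1026 (7.81%) at least 2-fold lower, and 11209 lay between. Of the higher genes 213, and of the lower genes 234, rest on a bound because 1 array was not well above background. At least 4-fold differences were seen for 210 higher and 214 lower genes.

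Across the 11969 genes measured on both arrays the correlation of the arrays was 0.965, which is across genes and not across independent replicates. The SD of the log2 difference was 0.73. The technical spread between spots was smaller, with a median SD of 0.027 for probes printed 10 times and 0.22 for the dim ones among them (6 probes). It leaves out differences in labelling and hybridization between the 2 arrays, and the spread between cultures. The software's error had a median of 0.20 over the measured genes. Among genes with several probes, 121 of the 163 higher and 146 of the 197 lower genes had every probe at least 2-fold apart in that direction. The 8 spike-in control probes had a mean difference of −0.24. Scaling on them instead moved the median gene to 0.24 and the share of higher genes among those at least 2-fold apart from 46.8% to 68.0%, and it adds 0.24 to every difference and list median, which turns the sign of values between −0.24 and 0. Among the 104 named genes at least 2-fold apart, 43 moved by over 1.5-fold after another background correction (normexp), all toward 0, and 14 did so with no filter on dim probes, 6 of them toward 0.

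**Figure D1:**
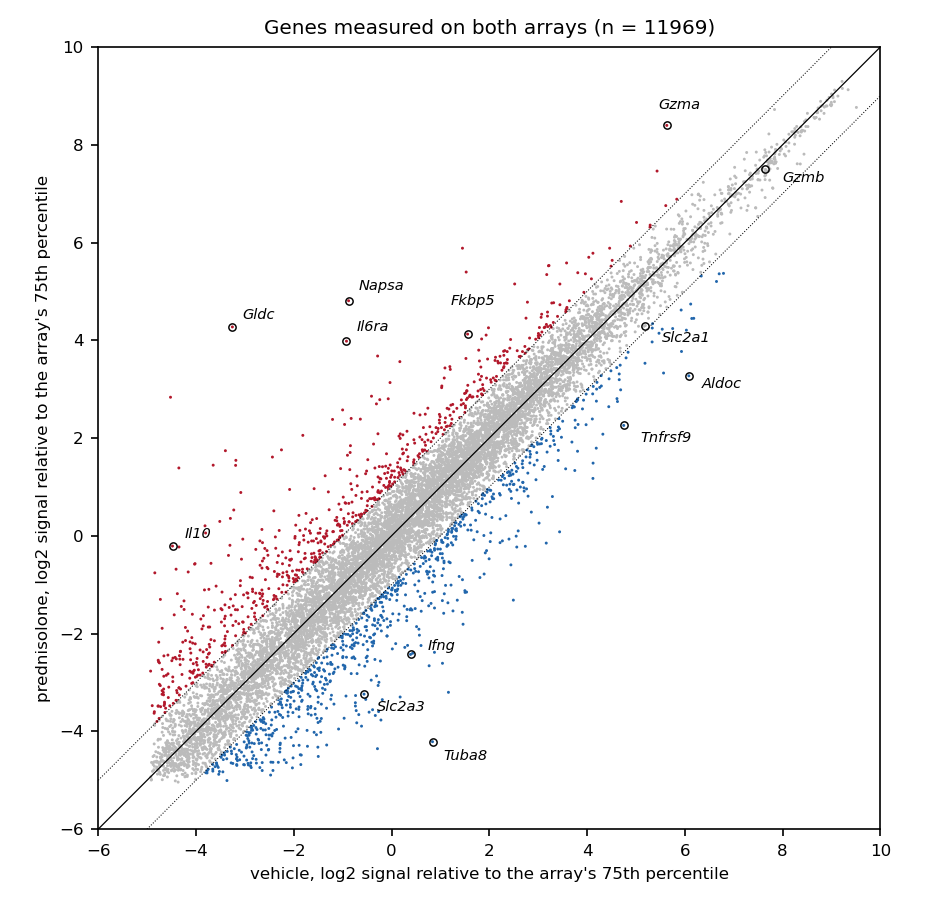
Each point is 1 of the genes measured on both arrays, with the vehicle array on the x axis and the prednisolone array on the y axis (log2 signal relative to the array's 75th percentile), and the lines mark 2-fold differences. Most genes lie between the lines, and 690 lie above and 792 below them.

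Of the 36 gene lists, 6 stood apart from random lists as higher and 9 as lower, where random draws of genes would give 1.8. Members of a list can vary together, so that number does not measure chance differences between 2 cultures. The glucocorticoid receptor targets had a median of 1.08 (95% interval over members 0.67 to 1.42), above all 10000 random lists of similar brightness. Of the 21 members with a value, 11 were at least 2-fold higher and none was lower by that much. Klf9, a transcription factor gene, was 9.37-fold higher (3.23 ± 0.20), Fkbp5, which encodes a chaperone partner of the receptor, was 2.57 ± 0.14, and Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, was 1.45 ± 0.14. The clock gene Per1 was 0.40 ± 0.20 and the receptor gene Nr3c1 was 0.60 ± 0.20. Zbtb16 was not well above background on either array.

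**Figure D2:**
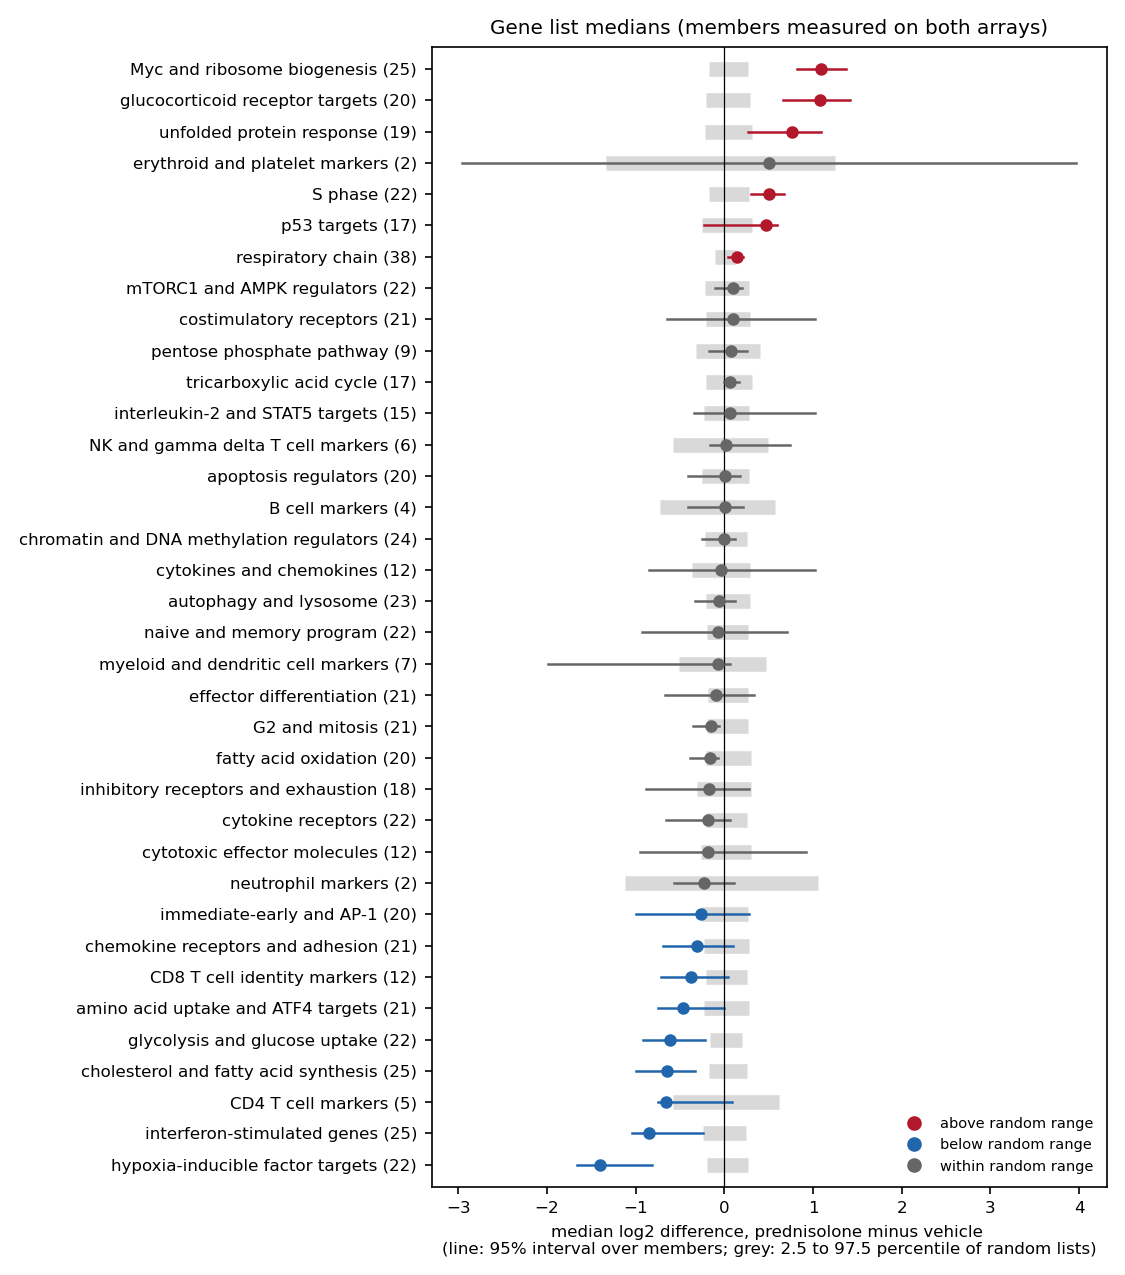
The median log2 difference of each of the 36 lists is drawn as a point with its 95% interval over members, and the grey band holds 95% of random lists of similar brightness. The HIF targets lie lowest at −1.40, and the Myc and ribosome biogenesis list lies highest at 1.09.

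The glycolysis and glucose uptake list had a median of −0.62 (−0.92 to −0.22), below all random lists, and −0.38 (interval to 0.02) under spike-in scaling. Of its 22 measured members 21 lay below 0 (spike-in scaling lifts those between −0.24 and 0 above it), and 5 were at least 2-fold lower (3 under spike-in scaling). Aldoc, which encodes an aldolase, was 7.01-fold lower (−2.81 ± 0.14) and Slc2a3 was −2.68 ± 0.22. Hk2, the gene of hexokinase 2, was 2.15-fold lower, and −0.86 under spike-in scaling. Slc2a1, the gene of the transporter GLUT1, was 1.85-fold lower (−0.89 ± 0.20). Pkm (−0.33 ± 0.14) and Ldha (−0.11 ± 0.14) lay closer to 0. The targets of HIF had a median of −1.40 (−1.66 to −0.82), also below all random lists, with 14 of 23 members at least 2-fold lower and none higher. Tmem45a was 6.23-fold lower (−2.64 ± 0.31) and Ero1a, an oxidase of the endoplasmic reticulum, was 4.71-fold lower (−2.24 ± 0.20). Pdk1, which encodes a pyruvate dehydrogenase kinase, was −0.90 ± 0.12, with probes from −1.25 to −0.22. Hif1a itself was 0.08 ± 0.20. After normexp the median of the HIF targets was −0.92, Slc2a3 was −1.63 and Tmem45a −1.11.

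**Figure D3:**
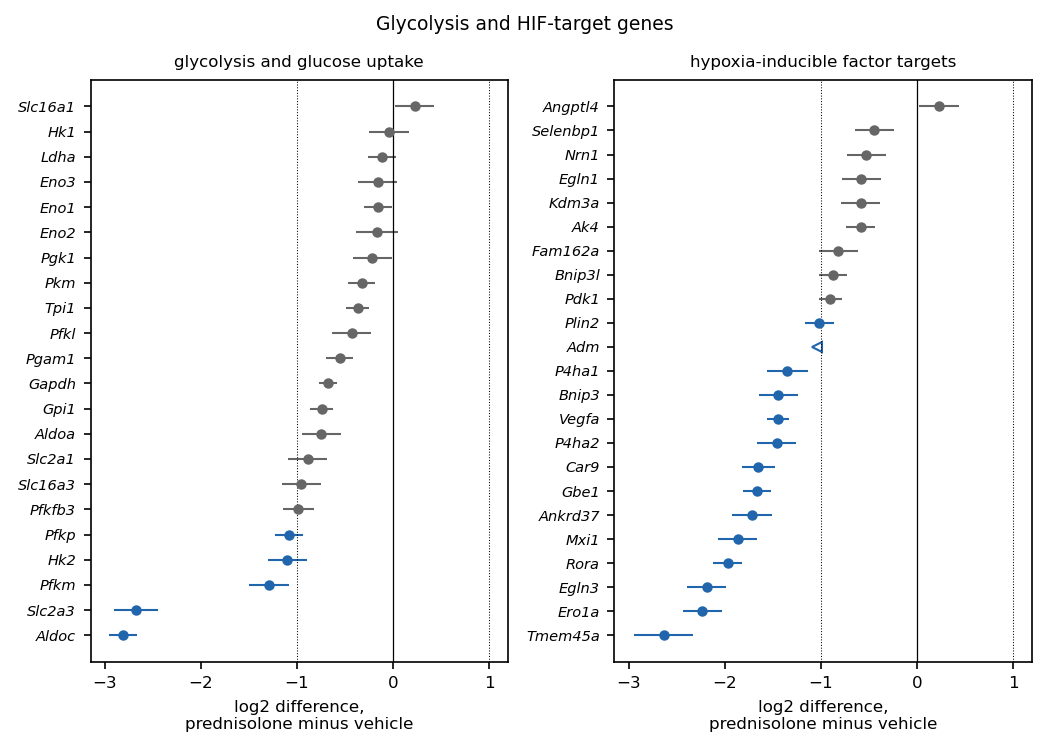
Each point is the log2 difference of a member of the glycolysis list (left) or the HIF-target list (right), with the software's error as a line, and an arrowhead is a bound. All glycolysis members except Slc16a1 (0.23, named after its value was seen) lie below 0, and spike-in scaling lifts those between −0.24 and 0 above it.

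The other lists of carbon metabolism lay near 0. The pentose phosphate pathway had a median of 0.08 (percentile 56.4), with G6pdx at 0.77, and the tricarboxylic acid cycle had 0.07 (percentile 56.6), with Idh3a at 0.70. Fatty acid oxidation had −0.16 (percentile 5.32), with Acadl at −0.92. None of the measured members of these lists was 2-fold apart, leaving out spots with an outlier flag. The respiratory chain had a median of 0.14 (0.05 to 0.21) at percentile 98.2, with Cycs, the gene of cytochrome c, as the member at least 2-fold higher of 38. It no longer stood apart under 7 other settings, at percentiles down to 93.1. Among the regulators of mTORC1 and AMPK (median 0.10, percentile 71.8) 3 of 22 were higher (1 after normexp) and 1 was lower. Txnip, which restrains glucose uptake, was 4.82-fold higher (2.27 ± 0.14), Deptor was 1.11 ± 0.28, or 0.44 after normexp, and Sesn3 was 3.20-fold lower.

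Cholesterol and fatty acid synthesis had a median of −0.65 (−0.997 to −0.33), below all random lists, with 7 of 25 members at least 2-fold lower (3 under spike-in scaling). The sterol enzymes Hmgcs1 (−1.73 ± 0.20) and Msmo1 (−1.53 ± 0.20) were lowest, while the fatty acid elongase gene Elovl6 was 1.42 ± 0.20. Amino acid uptake and targets of the stress factor ATF4 had a median of −0.46 (−0.74 to −0.01) at percentile 0.03, with 6 of 21 lower, among them Nupr1 (7.20-fold) and Ddit3 (6.39-fold).

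The list of Myc and ribosome biogenesis had a median of 1.09 (0.81 to 1.37), above all random lists, and 14 of 25 members were at least 2-fold higher. Srm, the gene of spermidine synthase, was 3.43-fold higher (1.78 ± 0.12) and Ncl, which encodes nucleolin, was 1.81 ± 0.21, or 1.11 with spots carrying an outlier flag kept. Myc itself was 0.81 ± 0.15. The list of the unfolded protein response had a median of 0.76 (0.26 to 1.09), above all random lists, with 8 of 19 higher. Ddit3, 6.39-fold lower among the ATF4 targets above, is not in this list, so its median does not speak for every branch of the response. Among its members, the transcription factor gene Xbp1 was 2.80-fold higher (1.48 ± 0.12) and Sdf2l1 was 2.68-fold higher. Autophagy and lysosome genes had a median of −0.06 (percentile 23.7), with 1 of 23 higher and 1 lower, Mitf (1.75 ± 0.34) and Ulk2 (−1.11 ± 0.15). After normexp neither was 2-fold apart (0.59 and −0.85).

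**Figure D4:**
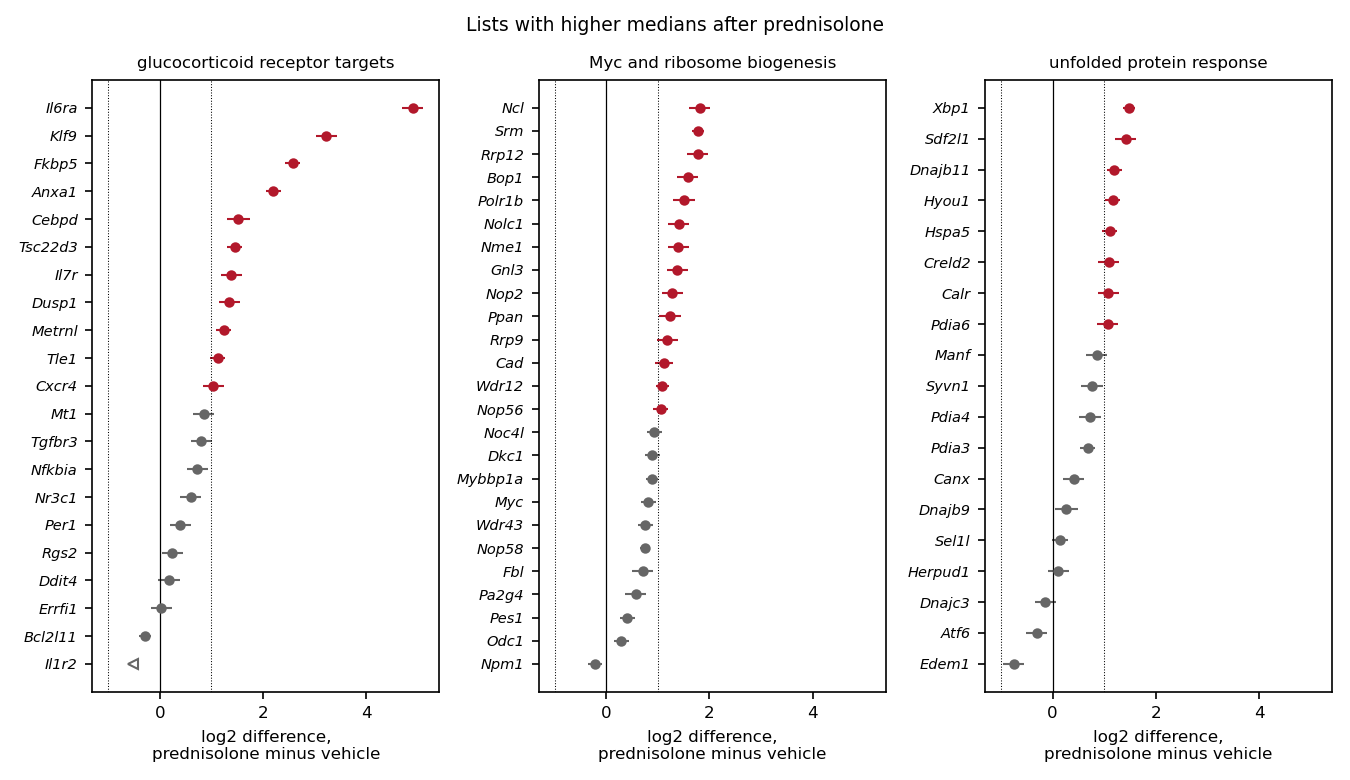
Each point is the log2 difference of a member of the lists that lay highest, with the software's error as a line. In the Myc and ribosome biogenesis list 24 of 25 members lie above 0, and the other lies between −0.24 and 0, which spike-in scaling lifts above 0.

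Genes of S phase had a median of 0.50 (0.31 to 0.68), above all random lists, and Ccne1, the gene of cyclin E1, was the 1 member of 23 at least 2-fold higher (1.16 ± 0.20), where spike-in scaling gave 5. Genes of G2 and mitosis had −0.15 (−0.35 to −0.06) at percentile 4.89, with no member 2-fold apart and Cenpf at −0.76 ± 0.20. Targets of p53 had a median of 0.47 at percentile 99.8, although the interval over members reached from −0.23 to 0.59. Aen (1.52 ± 0.14) and Pmaip1 (1.27 ± 0.20) were the members at least 2-fold higher of 17. Regulators of apoptosis had a median of 0.01 (percentile 50.4) and a mean of −0.14, with Bcl2l2 2.54-fold lower. Regulators of chromatin and DNA methylation had a median of −0.01 (percentile 43.5) with 2 of 24 lower, Jarid2 (−1.39) and Kdm6b (−1.09), both within 2-fold under at least 1 other setting.

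Among cytotoxic effector molecules 3 of 12 were at least 2-fold higher and 3 lower, with a median of −0.19 (percentile 6.58). The granzyme gene Gzma was 6.80-fold higher (2.77 ± 0.20), Gzmk was 4.34-fold lower (−2.12 ± 0.22) and Gzmb was −0.15 ± 0.20. Fasl, the gene of the death ligand, was 3.95-fold lower, and the serpin gene Serpinb9 was 2.32-fold higher. Prf1, the perforin gene, and Pdcd1 had only spots with an outlier flag and have no value here. Cytokines and chemokines went both ways, with 4 of 16 higher and 3 lower, a median of −0.04 (percentile 48.6) and a mean of 0.20. Il10, the gene of an immunosuppressive cytokine, was 19.3-fold higher (4.27 ± 0.31) and Il4 was at least 38.4-fold higher. Ifng was −2.81 ± 0.21 and Tnf was 0.84 ± 0.15. After normexp Il10 was 2.27 and Ifng −2.13. With a stricter filter on dim probes the cytokines stood apart as higher (0.61), and with flag-carrying spots kept the median of cytokines and chemokines was −0.30 (percentile 3.62), with 6 of 20 lower. Interferon-stimulated genes had a median of −0.85 (−1.04 to −0.24), below all random lists, with 11 of 27 lower, among them Usp18 (8.96-fold) and the helicase gene Dhx58 (5.17-fold). The exonuclease gene Isg20 was 3.25-fold higher. After normexp the median of this list was −0.47, still below all random lists, with 5 lower, and under spike-in scaling 6 were lower.

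Inhibitory receptors and exhaustion genes had a median of −0.17 (percentile 14.2), with 4 of 19 at least 2-fold higher and 5 lower (2 under spike-in scaling and 3 under 3 other settings). Havcr2, the gene of TIM-3, was 3.43-fold higher and Tigit 3.16-fold higher, whereas Lag3 was 5.55-fold lower (−2.47 ± 0.15) and the ectonucleotidase gene Entpd1 3.64-fold lower. With the stricter filter this list stood apart as lower (−0.67), as did the costimulatory receptors (−0.23). Costimulatory receptors had a median of 0.10 (percentile 69.6), with 7 of 21 higher (3 after normexp) and 4 lower. Icos was 4.95-fold and Tnfrsf25 4.74-fold higher, and Tnfrsf9, the gene of 4-1BB, was 5.63-fold and Slamf7 5.18-fold lower. Cytokine receptors had a median of −0.18 (percentile 4.14), with 2 of 23 at least 2-fold higher and 1 lower, and 13 of the 22 measured members below 0. Il6st was 2.15-fold lower (−0.87 under spike-in scaling and −0.84 after normexp, log2), and Il7r was 1.39 ± 0.20 and Il2ra 1.03 ± 0.20, the latter 0.98 without scaling. In the list of interleukin-2 and STAT5 targets (median 0.07, percentile 65.2) 5 of 15 were higher, such as Socs2 (4.10-fold), and Pim2 was 3.80-fold lower.

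**Figure D5:**
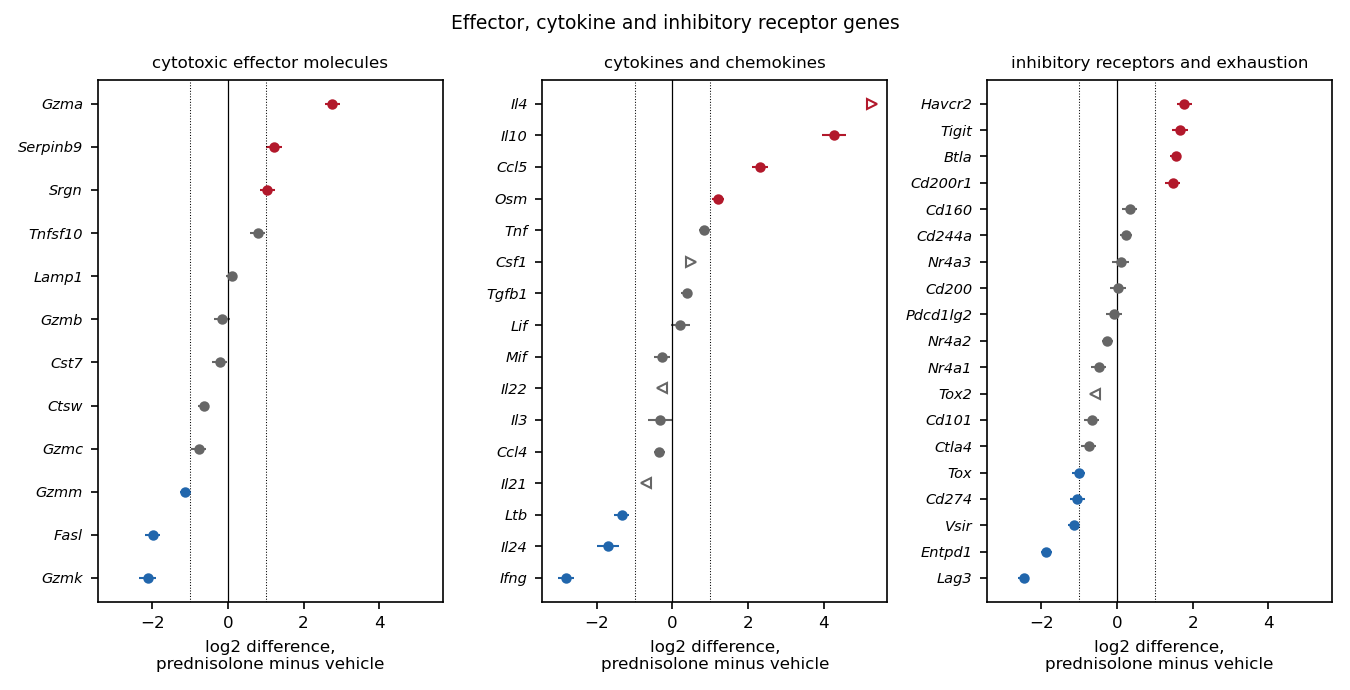
Each point is the log2 difference of a member of the lists of effector function, with the software's error as a line, and arrowheads are bounds. Members lie on both sides of 0, and the measured ones reach from Ifng at −2.81 to Il10 at 4.27.

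The naive and memory program had 6 of 22 members at least 2-fold higher and 6 lower, with a median of −0.07 (percentile 19.4). The memory-associated transcription factor genes Bcl6 (7.13-fold), Eomes (5.19-fold) and Tcf7 (3.33-fold, −1.74 ± 0.12) were lower, while Il6ra (29.9-fold) and Myb (2.98-fold) were higher. The lymph node homing gene Ccr7 was 2.001-fold lower, which was −0.76 (log2) under spike-in scaling. Effector differentiation genes had a median of −0.09 (percentile 13.7), with 3 of 23 higher and 6 lower. Irf4, a transcription factor gene induced by receptor signalling, was 2.11 ± 0.20, or 1.23 with flag-carrying spots kept, and Irf8 was 4.21-fold and Rora 3.93-fold lower. Tbx21 was −0.32 ± 0.20 and Prdm1 0.73 ± 0.20. Chemokine receptors and adhesion genes had a median of −0.30 (−0.69 to 0.09) at percentile 0.81, which was −0.10 with bounds, with Cx3cr1 at least 79.2-fold and Ccr4 8.18-fold higher, and Itgb3 3.56-fold and Cxcr6 2.58-fold lower. Immediate-early and AP-1 genes had a median of −0.26 (−0.99 to 0.27) at percentile 2.09, which was −0.19 with bounds, with 5 of 23 higher (2 after normexp) and 6 lower. Jun was 5.88-fold and Relb 3.34-fold lower, while Nfkb1 was 2.72-fold higher and Fos at least 5.90-fold higher, the latter 0.96 (log2) after normexp. Each of the last 2 lists lost its place outside the random lists under some other settings.

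Markers of CD8 T cells had a median of −0.38 (−0.71 to 0.04) at percentile 0.09, with none of 12 members 2-fold apart. Cd8a was −0.01 ± 0.14, Cd3e −0.42 ± 0.20 and Cd247 −0.95, with probes at −1.42 and −0.48. Markers of CD4 T cells had a median of −0.66 (percentile 1.67, 5 members), with 4 of the 5 below 0, such as Foxp3 (−0.75), and Cd4 itself, named after its value was seen, at 0.08 ± 0.20. That list fell inside the random lists under 2 other settings. Among markers of other cells, B cells had a median of 0.01 (percentile 64.3), with Vpreb3 at least 17.4-fold lower. NK and γδ T cells had 0.02 (percentile 58.9), with Cd163l1 2.66-fold and Klra8 at least 4.52-fold higher, the latter within 2-fold under at least 1 other setting. Myeloid and dendritic cell markers had a median of −0.07 (percentile 38.1) and a mean of −0.70, with Cd68 4.65-fold lower and Cd74 at least 4.61-fold lower, the latter −0.74 (log2) after normexp. Neutrophil markers had −0.23 (percentile 29.0) from 2 members, with Cxcr2 at least 5.69-fold higher. Erythroid and platelet markers had 0.51 (percentile 86.0) from 2 members, Hba-a1 (15.7-fold higher) and Epor (7.75-fold lower).

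Among genes measured on both arrays, leaving out predicted-gene, clone and accession-like symbols, the largest differences were Gldc, the gene of glycine decarboxylase, at 185-fold higher (7.53 ± 0.23), the lactate dehydrogenase gene Ldhd at 53.4-fold and the protease gene Napsa at 51.6-fold. After normexp Gldc was 6.202, Ldhd 3.86 and Tuba8 −3.20 (log2). Il6ra and Il10, named above, were also among the 10 highest, with Ccdc180, Bcl2l15, M1ap, Chil5 and Serf1, which were 21.6-fold to 35.3-fold higher. The lowest was the tubulin gene Tuba8 at 33.1-fold lower (−5.05 ± 0.28), followed by the interferon-inducible gene Ifi214 at 20.6-fold, Cbfa2t3 at 16.8-fold and Dapk2 (−3.81 ± 0.21). The complement gene C3 was 12.6-fold lower, with probes at −5.10 and −2.20. Samd3, Slc7a3, Tspoap1, St3gal6 and Pdgfb were 10.1-fold to 11.1-fold lower. Among genes seen well above background with prednisolone only, Trnp1 was at least 1666-fold higher, the urokinase receptor gene Plaur at least 239.6-fold and Spink2 at least 55.1-fold. With vehicle only, Cox6a2 was at least 49.0-fold, Pik3ap1 at least 27.8-fold, Grtp1 at least 26.9-fold and Zfp618 at least 17.9-fold lower with prednisolone. These bounds rest on 1 probe each and hold under the main setting, and bounds can shrink after normexp, as those of Cd74 and Fos did.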

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

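The genes in this part were chosen after their values were seen, and the test of the local background was set before its value was read. Spots with an outlier flag were not used in the comparison. Among 63 genes of the lists and anchors that had only such spots, 5 were at least 2-fold higher with prednisolone and 10 lower. The 5 higher ones were Nop16 at 1.06 (log2), Pcx at 1.47, Klf2 at 2.0, Sgk1 at 3.60 and Pdcd1 at 4.54. The 10 lower ones were Csf2 at −2.62, Xcl1 at −2.52, Chac1 at −1.89, Dapl1 at −1.73, Scd1 at −1.45, Lta at −1.41, Fdps at −1.27, Fdft1 at −1.22, Ndrg1 at −1.20 and Hdac7 at −1.02. Probes without a gene name were not used either, and 334 of the 7753 measured on both arrays were at least 2-fold brighter with prednisolone, against 354 dimmer.

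Pdcd1, the gene of the inhibitory receptor PD-1, had a signal well above background on both arrays, and its flag came from the local background on the prednisolone array. That local background was not raised, at 23 intensity units beside a spot of 7523, or 0.31% of it, where the median background of that array was 28. The test excludes little, because the processed signal is already background-subtracted and a raised background could hardly have brightened it. On the vehicle array the background was 26 beside a spot of 394. The difference may lie in the cells, but 1 array per condition leaves open whether it follows prednisolone or another difference between the cultures, and no biological explanation was tested.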

How the results depend on the processing

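Removal of the brightness and position trends was chosen after the data were seen. No paired analysis was possible because each condition had 1 array, and for the same reason no replicate could be left out. Normexp on the mean spot brightness, the planned form, was not run, and the median brightness stood in for it. Of the 15 lists that stood apart, 11 did so under every setting run that gives a percentile. Some of these settings could not change a percentile, because they shift every difference by the same amount. They are the median of measured probes, no scaling, spike-in scaling and the deposited table. Among 104 named genes at least 2-fold apart, 86 stayed so under all 12 settings run on genes. A further 5 (Cxcr2, Epor, Tmem45a, Vpreb3 and Zfp618) stayed so under the other settings but had no value with the stricter filter. Those that did not were Ccr7, Cd74, Deptor, Fos, Hk2, Il24, Il2ra, Il6st, Jarid2, Kdm6b, Klra8, Mitf and Ulk2, and under the settings run none of the 104 genes, and none of the 15 lists, changed sign. The 11 lists chosen later were not run under them. The cause of these shifts was not tested except where stated. The technical spread stayed within its range when flagged spots were kept. For B cell markers the stricter filter left no measured member.

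As reported, the genes higher with prednisolone numbered 903 and the genes lower with prednisolone 1026. The counts were 1429 and 671 with spike-in scaling, which moved the median of all measured genes to 0.24, 429 and 434 after normexp, whose offset shrinks differences of dim genes, and 513 and 505 with the stricter filter, which keeps fewer genes. They were 1460 and 1701 with no filter, which adds genes near background, 2053 and 2189 at 1.5-fold, and 355 and 416 at 3-fold. All 903 higher and 671 of the 1026 lower genes were shared with spike-in scaling.

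The uniform shift of 0.24 under spike-in scaling accounts for these medians, whose percentiles it leaves as they were: pentose phosphate pathway 0.31, tricarboxylic acid cycle 0.31, respiratory chain 0.38, fatty acid oxidation 0.082, S phase 0.74, G2 and mitosis 0.085, apoptosis 0.25, p53 targets 0.71, chromatin 0.23, autophagy 0.18, mTORC1 and AMPK 0.34, B cell 0.25, and myeloid markers 0.17. Quantile normalization moved the tricarboxylic acid cycle to −0.008.

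Respiratory chain no longer stood apart with quantile normalization (0.13), normexp (0.12), the stricter filter (0.12), no filter (0.14), the brightest probe (0.12), brightness trend removed (0.16) or unmatched random lists (0.14). The immediate-early list lost its place with normexp (−0.18), the brightest probe (−0.26), position trend removed (−0.23) and unmatched lists (−0.26). Chemokine receptors did with no filter (−0.091) and with flagged spots kept (−0.20), and CD4 markers with normexp (−0.45) and the stricter filter (−0.53). G2 and mitosis came to stand apart with normexp (−0.22), flagged spots kept (−0.16) and brightness trend removed (−0.21). With the stricter filter, so did cytokines (0.61), inhibitory receptors (−0.67), costimulatory receptors (−0.23), effector differentiation (−0.20) and erythroid markers (3.97, which is Hba-a1 alone).

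After normexp 43 of the 104 named genes moved by over 1.5-fold, all toward 0. On the dimmer array their median signal was −4.21 (log2, relative to the 75th percentile), against 0.91 for the other 61. With no filter 14 moved by over 1.5-fold, 6 of them toward 0.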

Other observations

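The tests of array scaling and of a brightness trend, and the tests on the glycolysis and unfolded protein response lists, were chosen only after their results were seen, and the position correction and 11 further lists were chosen after the data were seen. For the glycolysis and unfolded protein response lists the interval was first to stay at least 0.3 from 0. The reported intervals failed that bound, since they came as near to 0 as −0.22 and 0.26. The bound was then loosened to 0, after the values were seen.

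Of the 11 further lists, 3 stood apart as higher and 6 as lower by the median of the measured members, 1 of the 6 being the type 2 cytokine list, whose direction turns with bounds. Mitochondrial ribosomal proteins (median 0.28, percentile 99.98), purine and pyrimidine synthesis (0.40, percentile 99.6) and subunits of RNA polymerases I and III (0.79, percentile 99.99) were higher. Of the 15 polymerase subunits 6 were at least 2-fold higher. Cytosolic aminoacyl-tRNA synthetases (−0.23, percentile 1.66), cytosolic ribosomal proteins (−0.09, percentile 2.32), genes of MHC class I presentation (−0.29, percentile 0.54) and replication-dependent histones (−0.22, percentile 0.35) were lower relative to random lists. Spike-in scaling, which adds 0.24, lifts these 4 medians above 0 except that of MHC class I. It moves the random lists equally and leaves the percentiles as they were. Intervals over members included 0 for the synthetases (−0.38 to 0.01), MHC class I (−0.44 to 0.04) and purine and pyrimidine synthesis (−0.001 to 0.73). The cytosolic chaperonins (0.12, percentile 75.04) and the proteasome (0.21, percentile 97.4) lay inside the random lists.

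Genes linked to type 2 cytokines had a median of −0.68 (percentile 0.69) over 7 members, a mean of 0.11 and, with bounds included, a median of 0.65, so no direction is given for them. The haemoglobin genes Hba-a1 (3.97 ± 0.17) and Hba-a2 (4.01 ± 0.21) were higher with prednisolone and Hbb-bt was 0.87 ± 0.21, while Hbb-b1 and Alas2 were not well above background on either array. Of the MHC class II genes H2-Ab1 was −0.91 ± 0.12 and H2-Eb1 −1.99 ± 0.34. Ms4a1, Cd79a, Lyz2 and S100a8 were not well above background on either array, but Siglech, Itgam, Ly6g, Cd22 and Cr2, from the same marker lists, were so on both. Their signals differed widely. Cr2 was dimmest at 31.4 (vehicle) and 32.6 (prednisolone) intensity units, and Siglech was brightest at 37517 and 37873. The arrays' 75th percentiles were 400.4 and 386.9. Why Siglech was so bright was not tested. These genes were named after their values were seen.

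For the lower HIF-target and glycolysis lists, array scaling was examined first for the HIF targets. Their median nearest to 0 among the scalings was −1.16 (interval to −0.58) with the spike-ins, and it was −0.92 after normexp background correction. The scalings tried moved the median gene to 0.24 at most, so they could not have brought a median of −1.40 near 0. A shift of that size was argued against as the whole cause, and a larger error of scaling was not tested. A trend with brightness (−1.37 once removed) and with position (−1.39 once removed) was argued against too. For glycolysis the scaling stays open, since spike-in scaling gave −0.38 with an interval to 0.02. The list stayed below all random lists, but that scaling moves them equally, so this does not bear on the question. A second hypoxia-response list, also chosen after the data were seen, shares no gene with the preset lists. It had a median of −0.61 at percentile 0.000, with 5 of 21 members at least 2-fold lower and 2 higher. The pattern thus extends to other hypoxia-response genes. Lower activity of a hypoxia-response program may account for it, but a further list of such genes cannot tell the cause. Oxygen or cell density in the wells was not tested.

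For the higher Myc and ribosome biogenesis and unfolded protein response lists, array scaling was examined first for the former. Its median nearest to 0 among the scalings was 1.04 without scaling (1.01 after normexp). Here too the scalings tried could not have brought the median near 0, so only a shift of their size was argued against. Trends with brightness (1.06 once removed) and position (1.14 once removed) were argued against as well. For the unfolded protein response the median was at least 0.70 (quantile normalization) under the scalings and with either trend removed. Its interval nearest to 0 started at 0.21 (no scaling). This failed the bound first set for this list and passed only the one loosened after the values were seen. The test took scaling and trends together, so both stay open for this list, although none of those tried brought its median near 0. Of 4 further growth-related lists, 3 stood apart as higher and the aminoacyl-tRNA synthetases as lower, and the polymerase list kept a median of 0.64 without the 1 gene it shares with the preset lists. Cytosolic ribosomal proteins were also lower relative to random lists (−0.09). Spike-in scaling lifts their median and that of the synthetases above 0, but it moves the random lists equally. Both lists therefore stay lower relative to random lists and go against a wider growth program. The chaperonins did not stand apart, and the proteasome lay at percentile 97.4, just inside the random lists. A wider growth program may account for part of the pattern, with growth rate and culture density untested.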
